A study of Mus musculus with 8 samples.

How the data were processed

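The study measured gene expression in single cells of the mouse subventricular zone (SVZ) by Drop-seq, in which each cell is captured in a droplet with a barcoded bead and each transcript molecule is counted by a unique molecular identifier (UMI). Per the labels, the animals carried the CGD transgene, in which Nestin sequences drive a Cre recombinase that tamoxifen turns on, a histone-bound green fluorescent protein (GFP) and the diphtheria toxin receptor, joined by self-cleaving peptides. Per the labels' protocols, whole SVZ was dissected, viable cells were sorted by flow cytometry, and libraries were sequenced on a NextSeq 500 with a second read of 64 bases. Per the submitters' processing notes, the genome builds were mm10 and GRCm38. The aligner, the counting program and the rule by which barcodes were kept are not given in the sources used here. The deposited file of each sample held a raw UMI count for every gene and cell barcode, as whole numbers with no normalization. The 3 tables deposited for the whole series were not used here, since they hold the values of the sample files joined, in 1 table for part of the cells and in another after a natural log transform of 1 plus the count. Genes are named by the symbols in the files, and no coordinates were used.

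There were 8 libraries with 1 sample per group. In the sort experiment, at an age of 2 months, the groups were GFP high, GFP low, GFP negative and an unsorted library of viable cells. In the age series, all viable cells were taken at 2 weeks, 2 months, 6 months and 12 months. The files held 11017 barcodes, 6600 of the sort experiment and 4417 of the age series, with 11966023 UMIs over 27837 genes. The total was 1638979 UMIs for GFP high, 2633834 for GFP low, 931593 for GFP negative and 2061644 for the unsorted library. In the age series it was 1503804 UMIs at 2 weeks, 1163894 at 2 months, 1281603 at 6 months and 750672 at 12 months.

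Barcodes with fewer than 400 UMIs were left out (1917 barcodes), since their transcripts are too few to class a cell. Scrublet, as run in scanpy 1.11.5 with an expected doublet share of 5%, called 126 doublets (1.38% of the rest), which were left out. The remaining 8974 cells were scaled to 10000 UMIs and log transformed, 2000 variable genes were chosen within libraries, values were capped at 10 after scaling, and 30 principal components were kept. The 15 nearest neighbours of each cell were found exactly, joined by their Jaccard overlap with a minimum of 1 over 15, and clustered by the Leiden method at resolution 1, which gave 18 clusters. No batch correction was applied. A cluster took the name of the cell class with the largest share of its fixed markers at least 2-fold higher in the cluster than outside it, when at least 3 markers passed and the share led the next class by at least 0.1. Marker sets were written for astrocytes and quiescent neural stem cells (NSCs), which were given 1 marker set and form 1 class here, and for dividing progenitors (activated NSCs and transit-amplifying cells), neuroblasts, mature neurons, oligodendrocyte precursors, oligodendrocytes, ependymal cells, choroid plexus, microglia, border macrophages, T cells, other leukocytes, endothelial cells, pericytes with smooth muscle, fibroblasts and erythrocytes. No cluster took the name of choroid plexus, border macrophage, T cell, other leukocyte or fibroblast, and cluster 17, in which leukocyte sets tied, stayed unnamed. The astrocyte and NSC class, dividing progenitors and neuroblasts together are called the stem cell lineage. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.

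Shares of cells carry exact binomial (Clopper-Pearson) 95% confidence intervals (CIs), and levels in UMIs per 1000000 (counts per 1000000, CPM) carry exact Poisson intervals. A ratio of transcripts between libraries is the ratio of summed CPM in a class, with the exact conditional binomial interval. A ratio of shares carries limits, also marked CI, that divide an end of one share's interval by the opposite end of the other's. These limits are not exact 95% intervals of the ratio. For a count of 0, limits of shares and ratios given as at least a value take 3 counts, and limits of levels are the upper end of the Poisson interval. All intervals and limits cover counting error only, except those of the comparison of sexes over several libraries, where each gene's ratio was stratified by library (Mantel-Haenszel) and cells were drawn anew 1000 times within library and sex. A class entered a ratio where both libraries held at least 20 cells of it, which left out oligodendrocytes against 2 weeks (5 cells there) and all ratios of endothelial cells, oligodendrocyte precursors, pericytes, ependymal cells and erythrocytes between ages, and of mature neurons between ages other than 6 months over 2 months. With 1 library per group there are no replicates, so no test was run and no p-value is given. The unsorted library of the sort experiment and the 2-month library of the age series share age and gate in the labels but not their mix of sexes, and the ratio between these libraries serves as a scale for other differences. For the share of dividing cells, each lineage cell was thinned at random to 400 UMIs and counted when it held at least 2 UMIs of the S and G2/M lists.

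The lists of genes covered S phase, G2/M phase, quiescent NSCs, activation and lineage commitment, radial glia and perinatal genes, dorsal and ventral position, immediate early and dissociation genes, interferon response, major histocompatibility complex (MHC) class I, homeostatic microglia, disease-associated microglia, chemokines and cytokines, cholesterol synthesis, glycolysis, myelin, ribosomal proteins, mitochondrially encoded genes, reactive astrocytes, and iron and oxidative stress. A list is described by its members with at least 10 UMIs over both libraries, its median log2 ratio, and the percentile of that median among the medians of 10000 random lists of equal size matched on mean expression. The classes, markers, lists, main comparisons and the rule for naming genes were fixed before the data were examined. Not among the comparisons fixed were the ratio of 6 months over 2 months and some comparisons of gates within a class. Nor was the naming of genes for GFP high over GFP low within the astrocyte and NSC class part of the fixed rule. Under that rule, genes had at least 50 UMIs over both libraries, a CI that excluded a 1.5-fold difference, and a log2 ratio larger in size than that between the pair of unsorted 2-month libraries. The 10 highest and the 10 lowest were taken per ratio, without mitochondrially encoded, ribosomal protein, hemoglobin and Y-linked genes, Xist, Tsix and predicted gene models. Members of the fixed lists are named as examples, and any other gene named outside the rule is marked as chosen after its values were seen.

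The procedure was tested on counts simulated with counting error only, with 2-fold and 4-fold changes set in known genes. Of the naming rule, the minimum of UMIs and the interval against 1.5-fold were applied there. The comparison with the unsorted 2-month libraries was not. For GFP high over GFP low in all cells, 10054 genes were run, and 96.0% of the intervals of all these genes held the true value. There 2 unchanged genes passed this part of the rule, which recovered 40% of 2-fold and 100% of 4-fold changes. In the stem cell lineage at 12 months over 2 weeks (4649 genes), 96.2% of intervals held, no unchanged gene passed, and 29% and 92% were recovered. In the astrocyte and NSC class at 12 months over 2 months (438 genes) recovery was 27% and 92%, in microglia (499 genes) 30% and 97%, and in oligodendrocytes (2036 genes) 29% and 97%, each with 1 unchanged gene past the rule.

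Alternatives fixed beforehand were Leiden resolutions of 0.5 and 2, 1000 variable genes, 15 principal components, doublets kept, at least 1000 UMIs per cell, each cell classed on its own by its highest mean marker score, and separate clustering of the sort and age libraries. For ratios they were the mean of per-cell values, totals without mitochondrially encoded and ribosomal protein genes, median-of-ratios scaling, no minimum or a minimum of 50 UMIs per gene, and the unsorted library of the sort experiment as the 2-month reference, and for dividing cells other depths of thinning (200, 800 or none) and other minimums (1 or 3 UMIs). Another random start, a minimum of 200 and a maximum of 4000 UMIs per cell, 15 principal components for some results, the list alternatives for lists without a planned one, interferon and immediate early medians without the small cluster led by genes of the same list, and other depths of thinning together with other minimums were added after the data were seen. Median-of-ratios scaling shifted the median log2 ratio of all genes by over 0.1 for GFP high over GFP low (0.18), GFP high over GFP negative (-0.19), GFP low over GFP negative (-0.34), the lineage between GFP high and GFP low (0.19), the astrocyte and NSC class at 12 months over 2 weeks (0.21), the lineage at 12 months over 2 weeks (0.12) and over 2 months (0.17), microglia at 12 months over 2 weeks (0.11), and dividing progenitors and neuroblasts at 12 months over 2 weeks and over 2 months (0.12 to 0.15).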

Results

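Single-cell transcriptomes were collected from the mouse subventricular zone (SVZ), the niche along the lateral ventricle in which neural stem cells (NSCs) give rise to dividing progenitors and then to neuroblasts. The animals carried a transgene in which Nestin sequences drive a nuclear green fluorescent protein (GFP), so that fluorescence marks the stem cells and is passed to their progeny. In the sort experiment, cells of mice aged 2 months were taken as GFP high (1325 cells after filtering, median 859 UMIs per cell), GFP low (1658 cells, 999 UMIs), GFP negative (1051 cells, 722 UMIs) or unsorted (1389 cells, 969 UMIs). In the age series, all viable cells were taken at 2 weeks (917 cells, 1237 UMIs), 2 months (987 cells, 839 UMIs), 6 months (1133 cells, 810 UMIs) and 12 months (514 cells, 1012 UMIs). Each of the 8 groups was 1 library of 750672 to 2633834 UMIs, so there were no replicates and no test was made. Every interval below covers counting error only, except those of the comparison of sexes over several libraries. The unsorted library and the 2-month library of the age series shared age and gate in the labels, though their mix of sexes differed, and the difference between them is given as a scale for the others.

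The first comparison asked which cells of the SVZ carry the reporter at high, low or no fluorescence. The astrocyte and NSC class made up 83.2% of GFP high cells (95% CI 81.1–85.2%), 25.7% of GFP low cells (23.6–27.9%) and 2.38% of GFP negative cells (1.55–3.49%), a 35.0-fold difference between the outer gates (CI 23.2–55.2). Dividing progenitors and neuroblasts peaked in the GFP low gate. Dividing progenitors were 34.1% of GFP low cells (31.8–36.4%) against 9.36% of GFP high cells (7.84–11.1%) and 5.23% of GFP negative cells (3.97–6.76%), and neuroblasts were 32.6% (30.4–34.9%) against 1.13% (0.635–1.86%) and 3.14% (2.17–4.38%). Oligodendrocytes were 58.7% of GFP negative cells (55.7–61.7%) and 4.40% of GFP low cells (3.47–5.50%), and microglia 15.98% of GFP negative cells (13.8–18.3%) and 1 cell in each of the other gates.

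The share of dividing progenitors was 3.64-fold higher in GFP low than in GFP high (CI 2.88–4.64), and the neuroblast share was 10.4-fold higher in GFP low than in GFP negative (6.93–16.1). The dividing cells of the 2 gates were not the same: 81 of those in GFP high lay in cluster 8 and 43 in cluster 5, while 349 of those in GFP low lay in cluster 5 and 216 in cluster 8. Microglia were 1 cell in GFP high and 168 cells in GFP negative, a 212-fold difference in share (CI 32.9–9600). Oligodendrocytes were 0 of 1325 GFP high cells, which allows a share of up to 0.226%, and at least 259-fold more of the GFP negative cells. The oligodendrocytes of GFP low were mostly of cluster 3 (67 of 73 cells), whereas GFP negative held 328 of cluster 6 and 283 of cluster 3. Ependymal cells, which line the ventricle with motile cilia, were 4.53% of GFP high cells (3.47–5.79%) and 0.181% of GFP low cells, a 25.0-fold difference (6.58–155). Mature neurons were 8.47% of GFP negative cells, 1.43% of GFP high cells and 0.362% of GFP low cells. The unnamed cluster 17, which held macrophage and lymphocyte transcripts, was 0 of the GFP high cells (up to 0.226%), 0.302% of GFP low, 0.190% of GFP negative and 0.720% of unsorted cells. The gate itself sets these shares, and the minimum of 400 UMIs removed 16.8% of GFP high, 10.1% of GFP low and 3.64% of GFP negative barcodes. At a minimum of 1000 UMIs the astrocyte and NSC share of GFP high was at least 57.0-fold that of GFP negative, the neuroblast ratio was 6.76 and the microglia ratio at least 10.7, while the dividing progenitor ratio was 6.45 with 15 principal components and 5.85 with the sort and age libraries clustered separately.

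**Figure D1:**
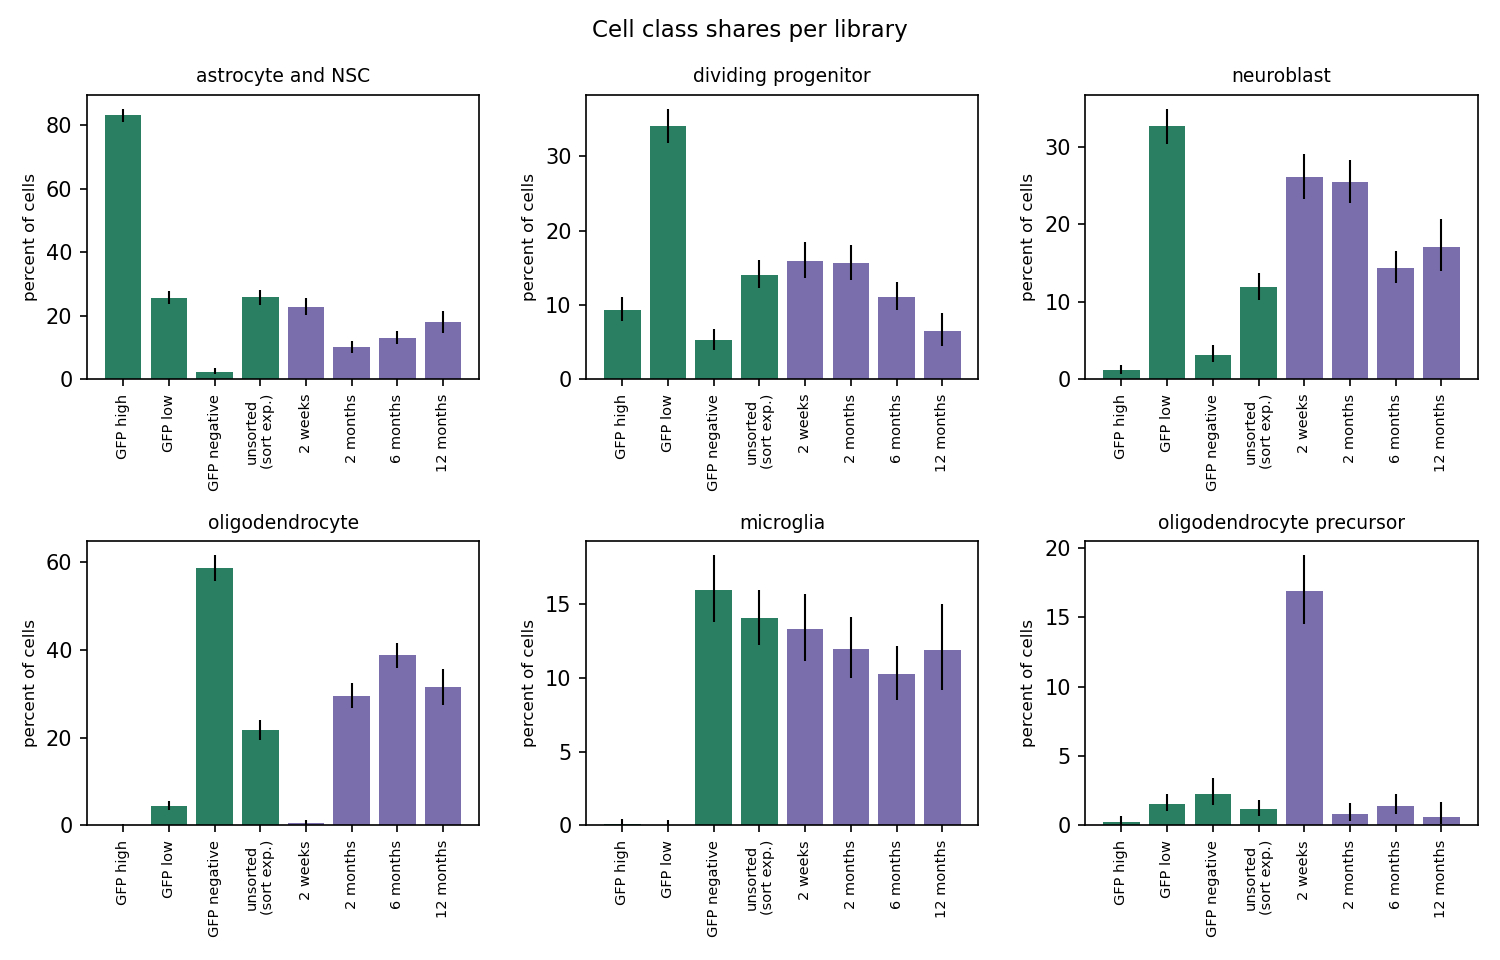
Share of cells in each class (vertical axes, % of the cells of a library) for the 8 libraries, as bars with exact binomial 95% intervals. The astrocyte and NSC class fell from 83.2% in GFP high to 2.38% in GFP negative, neuroblasts were highest in GFP low among the gates, and oligodendrocytes were 0.545% at 2 weeks and 29.6% at 2 months.

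Transcripts of astrocytes, of ciliated cells and of the reporter set GFP high apart from GFP negative. Thbs4, which encodes a secreted thrombospondin, was 253-fold higher in GFP high (CI 45.2–10031), Gfap, the intermediate filament of astrocytes, 118-fold (20.9–4667), and Acsbg1, which activates long-chain fatty acids, 125-fold (34.5–1037). Agt, Scara3 and Cyr61 were 108-fold, 160-fold and 170-fold higher. These genes, and Thbs4 and Gfap as well, held 1 UMI each in GFP negative, so the size of their folds is uncertain. The cilia genes Rsph1 and Ccdc153 were 139-fold and at least 72.7-fold higher (lower end of the interval 58.8), and Ccdc74a 67.0-fold. The row CGD1, read here as the transcript of the transgene from its name and from its levels by gate, so that this contrast is in part how it was identified, stood at 558 UMIs per 1000000 (counts per 1000000, CPM) in GFP high (521–596) and 8.83 in GFP negative (3.81–17.4), a 63.2-fold difference (31.9–147). In the opposite direction lay myelin genes: Mal was 2749-fold lower in GFP high (760–22707), Mag 1704-fold (471–14076), Cldn11 1029-fold, Ermn 882-fold, Fa2h 794-fold and Mog 738-fold, together with Apod, a lipid carrier (1934-fold), and Ugt8a, which makes the galactolipid of myelin (1432-fold).

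Across the fixed lists, 16 of 17 measured genes of quiescent NSCs were higher in GFP high than in GFP negative, with a median log2 ratio of 3.66 against 0.62 between the unsorted 2-month libraries. Among them Id3 stood at 561 and 35.3 CPM, and S1pr1 at 677 and 30.9. Aldoc, of the glycolysis list, stood at 2750.0 and 78.3. The 11 myelin genes and the 12 homeostatic microglia genes were all lower, with medians of -9.78 and -5.69, the latter -3.81 at a minimum of 1000 UMIs per cell. Of 14 chemokine and cytokine genes 13 were lower (median -3.18). Cx3cr1, the fractalkine receptor of microglia, stood at 4.54 CPM in GFP high and 684 in GFP negative, and P2ry12 at 7.78 and 277. Ttr, the thyroxine carrier of the choroid plexus, was 742-fold lower in GFP high (132–29359), but 434 of its 436 UMIs in GFP negative lay in 1 cell.

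Over all cells, cell cycle genes and genes of lineage commitment set GFP low apart from GFP negative. The lineage was 92.4% of GFP low cells and 10.8% of GFP negative cells. Within the lineage, dividing progenitors were 36.9% in GFP low (34.5–39.4%) and 48.7% of 113 cells in GFP negative (39.2–58.3%). All 36 measured genes of the S and G2/M lists were higher in GFP low, each with an interval above no difference, at a median log2 ratio of 2.47 (1.88 at a minimum of 1000 UMIs per cell). Top2a, which untangles replicated DNA, stood at 919 CPM in GFP low and 191 in GFP negative, and Mki67, a mark of dividing cells, at 388 and 89.4. All 13 measured genes of activation and lineage commitment were higher (median 2.74), among them the homeobox gene Dlx2 (327 against 33.1). Of 97 ribosomal protein genes 89 were higher, with a median of 1.10 against -0.20 between the unsorted 2-month libraries. The 11 myelin and 12 homeostatic microglia genes were lower (medians -3.14 and -6.16, the latter -4.73 at that minimum of 1000 UMIs).

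Between GFP high and GFP low, over all cells, quiescence and cell cycle genes lay in opposite directions. Astrocytes and NSCs were 83.2% and 25.7% of these gates, and dividing progenitors 9.36% and 34.1%. The ratios of this paragraph therefore also carry the mix of classes, and the quiescence difference within the astrocyte and NSC class, given below, was smaller. All 17 quiescent NSC genes were higher in GFP high (median log2 ratio 1.88, against 0.62 between the unsorted 2-month libraries), and all 36 S and G2/M genes were lower (median -1.32, against 0.02; -1.90 by the mean of per-cell values), 35 of them with an interval below no difference. Apoe, the lipid carrier of astrocytes, stood at 17560 CPM in GFP high and 4369 in GFP low, Id3 at 561 and 102, and Vcam1, an adhesion molecule of quiescent NSCs, at 138 and 41.0. Cdk1, the kinase of mitotic entry, stood at 55.8 and 169. Of 13 activation and commitment genes 11 were lower (median -1.46), with Dlx2 at 47.4 and 327. Interferon response genes were higher for 15 of 16 (median 1.14, against -0.79), with a median of 0.997 without cluster 15, a small cluster of the astrocyte and NSC class led by genes of this list (25 and 8 cells), and glycolysis genes for 14 of 16 (median 0.99, against 0.46), including Aldoc (2750.0 and 574). Ribosomal protein genes were lower for 87 of 96 (median -0.46, against -0.20). Radial glia genes were higher for 11 of 12 (median 1.28), MHC class I genes for 9 of 12 (0.84), iron and oxidative stress genes for 8 of 11 (0.66), mitochondrially encoded genes for 15 of 19 (0.47, below the 1.20 between the unsorted 2-month libraries in size), and all 8 reactive astrocyte genes (1.21, or 1.89 at a minimum of 1000 UMIs per cell). Immediate early genes went both ways, with 9 of 16 higher (median 0.64), including Fos (2.05-fold), and Jun 1.12-fold lower.

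Genes of cilia and of myelin were among the single genes with the largest ratios between these gates. In GFP high, Cdhr4 was 52.7-fold higher (CI 14.0–444), Efcab1 50.3-fold, Calml4 43.9-fold, Ccdc113 40.5-fold, Fam216b 36.7-fold, Ppp1r36 34.1-fold, Wdr66 30.3-fold and Tmem212 30.04-fold (18.2–53.2). Of the 12 measured ependymal markers 11 were higher (median 4.20, against 0.15 between the unsorted 2-month libraries; 3.51 by the mean of per-cell values), beside the 4.53% of ependymal cells in that gate. Hdc, which makes histamine, was 42.6-fold higher (14.1–211), and Atf3, a stress-induced transcription factor, 29.8-fold, at 36.3 CPM in GFP high, 1.22 in GFP low and 105 in GFP negative. The 11 myelin genes were lower in GFP high (median -6.34), led by Mal (312-fold, 86.0–2576), Mag (193-fold), Opalin (89.2-fold) and Mog (80.8-fold), beside the 4.40% of oligodendrocytes in GFP low. Vtn, a pericyte transcript, was 64.5-fold lower (11.3–2572).

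Within the astrocyte and NSC class alone, the question was how GFP high cells differed from GFP low cells of the same class. The fixed naming of genes did not cover this comparison. Genes named here outside the fixed lists were therefore chosen after their values were seen. The reporter was 4.71-fold higher in GFP high (CI 3.47–6.52). Thbs4 was 2.07-fold higher (1.60–2.69), Fxyd6, a regulator of ion transport, 2.89-fold (1.96–4.41), Gsn, which severs actin filaments, 2.70-fold (1.83–4.13), Rlbp1, which binds retinaldehyde, 2.36-fold (1.58–3.65), and Enpp4, Fbxo2, Egln3 and Rwdd4a lay between 1.90-fold and 4.19-fold. Transcripts of neuronal cells were lower: Dlx1 stood at 11.7 CPM in GFP high and 105 in GFP low (8.92-fold, 4.57–18.7), Sox11 at 43.0 and 185 (4.30-fold, 2.91–6.43) and Tmsb10 at 31.3 and 198 (6.34-fold, 4.14–9.93). The libraries held 1.13% and 32.6% neuroblasts, and oligodendrocytes of GFP low, which should lack these genes, held 17.8 CPM of Dlx1 and 17.8 of Sox11 (2.15–64.2 each), in 2.74% of cells each against 4.93% and 10.3% of astrocytes and NSCs there, at median depths of 1314 and 751 UMIs. The background share of Tmsb10 was not measured here. All 11 measured neuroblast markers were lower (median log2 ratio -3.16, percentile 0 among random lists; -1.70 with at least 50 UMIs per gene and -4.09 at a minimum of 1000 UMIs per cell), as were all 10 measured G2/M genes (-2.15), while S and G2/M genes together went both ways (14 of 24 lower, median -0.20). UMIs of all G2/M genes stood at 187 CPM in GFP high (161–215) and 485 in GFP low (417–561), beside 9.36% and 34.1% dividing progenitors in the libraries and a background of 88.8 CPM in oligodendrocytes of GFP low (42.6–163). Of 12 measured genes of dorsal and ventral position 10 were higher (median 0.93, percentile 99.99), a median that was 0.30 at a minimum of 1000 UMIs per cell. Quiescent NSC genes showed a smaller difference, with 12 of 17 higher and a median of 0.23. Flrt1, Wnk2, Mtss1l, Kdm1a, Bdp1 and Usp7 were 2.95-fold to 3.23-fold lower.

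The row CGD1, whose identity as the transcript of the transgene is inferred, was followed through the classes and ages and is called the reporter here. Across all cells it stood at 558 CPM in GFP high, 286 in GFP low (266–308), 8.83 in GFP negative and 129 in unsorted cells (114–147). In the age series it stood at 266 at 2 weeks (240–293), 159 at 2 months (136–185), 86.7 at 6 months (70.8–105) and 18.0 at 12 months (9.31–31.5). In the astrocyte and NSC class the values were 639.5 at 2 weeks (550–739), 356 at 2 months (232–521), 297 at 6 months (204–417) and 35.1 at 12 months (7.23–103). In neuroblasts the values were 364 at 2 weeks, 328 at 2 months, 299.8 at 6 months and 29.2 at 12 months, and in dividing progenitors 219.7, 227, 111 and 65.3. In the lineage 2 weeks exceeded 12 months 9.15-fold (5.18–17.9), while the unsorted library and the 2-month library, of one age, held 218 and 284. At least 1 reporter UMI was found in 35.4% of lineage cells at 2 weeks and 4.69% at 12 months, against 0.820% and 0 of the microglia there, at median depths of 1209.5 and 941 UMIs in the lineage and 1106 and 1136 in microglia. Ependymal cells of GFP high held 926 CPM (761–1116), above the 568 of astrocytes and NSCs in that gate (523–616). Nes, the gene whose sequences drive the transgene, stood at 78.0 CPM in lineage cells at 2 weeks, 68.1 at 2 months, 89.7 at 6 months and 53.6 at 12 months, a 1.46-fold difference between the first and the last (0.827–2.74). In the astrocyte and NSC class Nes stood at 76.5 (22 UMIs), 13.7 (1 UMI), 8.99 (1 UMI) and 0 (up to 43.1), and at 68.0 in the unsorted library.

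**Figure D2:**
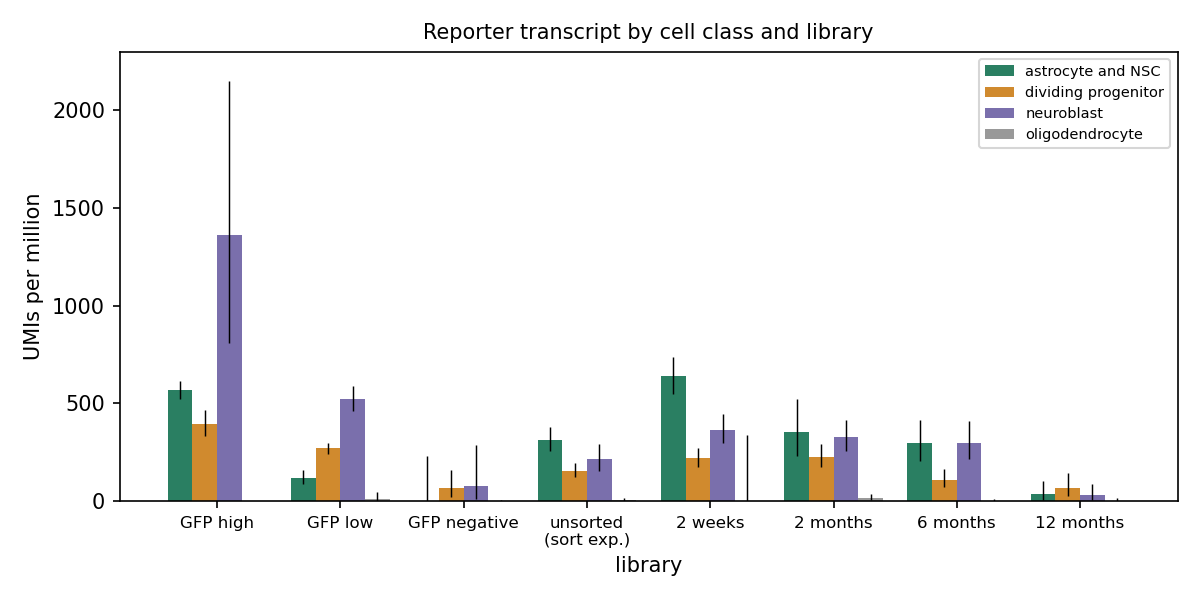
Reporter transcript (vertical axis, CPM) in the astrocyte and NSC class, dividing progenitors, neuroblasts and oligodendrocytes of each library, as bars with exact Poisson 95% intervals. The astrocyte and NSC class held 639.5 CPM at 2 weeks and 35.1 at 12 months, and oligodendrocytes 14.8 or less in the libraries that held any, with 0 from 5 cells at 2 weeks (up to 337).

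The age series asked how the cells of the SVZ and their transcripts differ from the second week of life to 12 months. Dividing progenitors were 24.6% of lineage cells at 2 weeks (CI 21.2–28.2%), 30.6% at 2 months (26.6–34.8%), 28.9% at 6 months (24.7–33.4%) and 15.5% at 12 months (10.9–21.1%). The ratio of 12 months to 2 weeks was 0.630 (0.386–0.995), larger in size than the 0.889 between the unsorted 2-month libraries. The share of lineage cells with at least 2 cell cycle UMIs, at 400 UMIs for every cell, was 25.3% at 2 weeks (21.8–28.9%), 33.5% at 2 months (29.4–37.8%), 28.7% at 6 months (24.5–33.2%) and 12.7% at 12 months (8.52–17.9%). The last was 0.502 of the first (0.294–0.821). It was 0.844 (0.642–1.09) for at least 1 UMI at 800 UMIs per cell, a depth that leaves out all cells with fewer UMIs. Without thinning the shares were 39.7%, 43.1%, 36.9% and 21.1%, at median depths of 1209.5, 805.5, 786 and 941 UMIs. Oligodendrocytes, which do not divide, gave a background of 0.342% at 2 months, 1.14% at 6 months and 2.47% at 12 months, at 1007.5, 858 and 1124.5 UMIs. Neuroblasts were 40.2% of the lineage at 2 weeks, 49.8% at 2 months, 37.4% at 6 months and 41.3% at 12 months, with a ratio of 1.03 between the last and the first (0.782–1.33). The same ratio was 0.461 between the unsorted 2-month libraries.

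**Figure D3:**
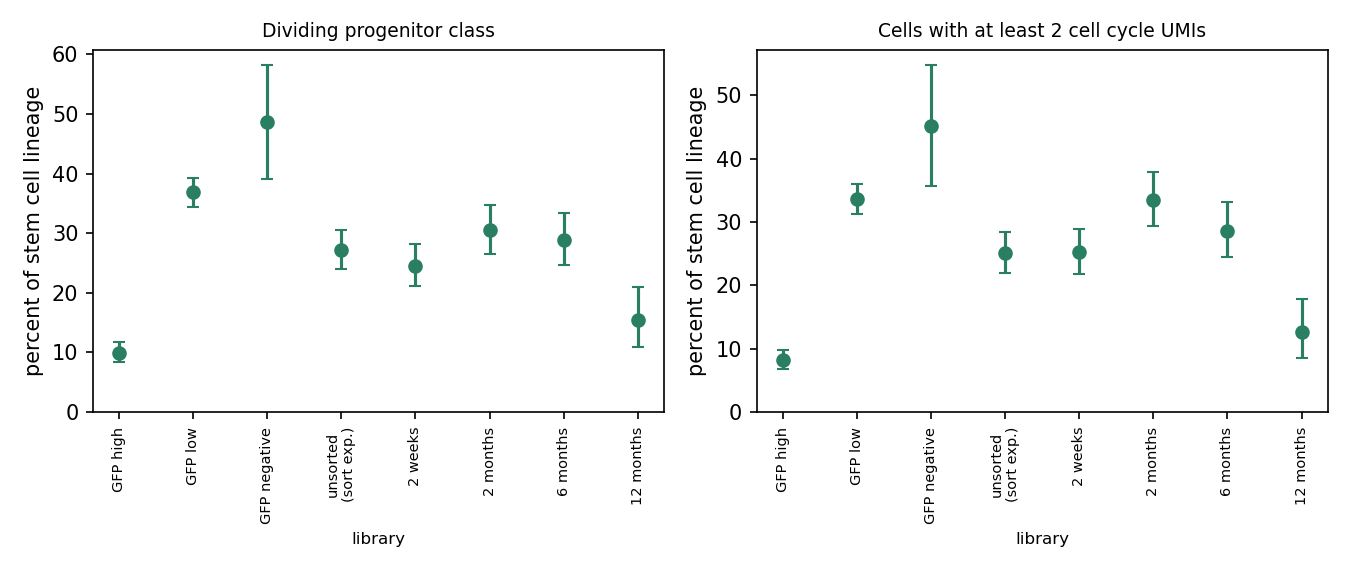
Dividing progenitors (left, % of stem cell lineage cells) and lineage cells with at least 2 cell cycle UMIs after thinning to 400 UMIs (right, % of lineage cells) in each library, as points with exact binomial 95% intervals. At 12 months the values were 15.5% and 12.7%, against 24.6% and 25.3% at 2 weeks.

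Outside the lineage, oligodendrocytes, their precursors and endothelial cells differed between ages. Oligodendrocytes were 0.545% of cells at 2 weeks (5 cells), 29.6% at 2 months (26.8–32.5%), 38.7% at 6 months (35.9–41.7%) and 31.5% at 12 months (27.5–35.7%), so that 2 months exceeded 2 weeks 54.3-fold (21.1–184). Their precursors ran the other way, at 16.9% at 2 weeks (14.5–19.5%), 0.811% at 2 months, 1.41% at 6 months and 0.584% at 12 months, a 29.0-fold difference between the first and the last (8.57–162). Endothelial cells were 1.53%, 1.32%, 2.91% and 6.03% in order of age, and 12 months exceeded 2 months 4.58-fold (1.84–12.0), against 2.19 between the unsorted 2-month libraries. Microglia were 13.3%, 12.0%, 10.2% and 11.9%. The astrocyte and NSC class was 22.8%, 10.0%, 12.97% and 17.9%, within the 2.57-fold difference between the unsorted 2-month libraries (25.8% and 10.0%). The unnamed cluster 17 was 0.327%, 0.405%, 0.353% and 1.36%. The minimum of 400 UMIs removed 7.59% of barcodes at 2 weeks, 20.2% at 2 months, 13.8% at 6 months and 37.8% at 12 months, and dividing progenitors were deeper than other cells (2223 against 941 UMIs in the whole lineage at 12 months), so these shares rest on what passed it. Xist, the X-inactivation RNA, was chosen after its values were seen. It stood at 0 CPM at 2 weeks (up to 2.52), 848 at 2 months, 341 at 6 months and 1503 at 12 months. The Y-linked Eif2s3y stood at 144, 0, 55.6 and 0, so the mix of sexes differed between the ages. Every ratio of 2 or 12 months over 2 weeks therefore also sets a library without Eif2s3y against one without Xist. In those ratios age and sex cannot be told apart. The comparison of sexes made below for interferon and MHC class I genes did not decide between them. The mix of sexes differed between the libraries of 2 months as well, with Xist at 493 and Eif2s3y at 51.5 in the unsorted library.

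In the lineage as a whole, cell cycle genes were lower at 12 months. Against 2 weeks, 31 of 36 S and G2/M genes were lower, 7 with an interval below no difference (median log2 ratio -0.33, interval of the median -0.49 to -0.22, against -0.15 between the unsorted 2-month libraries). Against 2 months, all 18 G2/M genes were lower, 13 with such an interval (median -0.89, against -0.34). In order of age, Mki67 stood at 338, 473, 511 and 232 CPM, Cenpf, a kinetochore protein, at 271, 405, 448 and 164, and Ube2c, which drives mitotic exit, at 238, 401, 277 and 139. Of genes named by the rule, Prc1, which bundles spindle microtubules, stood at 288, 504.5, 432 and 114 (4.42-fold lower at 12 than at 2 months, CI 3.06–6.58), Spc25 at 203, 405, 294 and 78.6 (5.16-fold, 3.32–8.40), Kif23 at 53.1, 123, 93.8 and 21.4 (5.76-fold, 2.51–16.2) and Ccng2 at 65.0, 162, 87.6 and 21.4 (7.56-fold, 3.34–21.2). The median against 2 weeks was -0.76 by the mean of per-cell values and -0.11 at a minimum of 1000 UMIs per cell. Quiescent NSC genes were higher at 12 than at 2 months for 15 of 17 (median 0.99), but by 0.32 against the unsorted library as the 2-month reference. Moving with them, the astrocyte and NSC class was 35.2% of the lineage at 2 weeks, 19.6% at 2 months, 33.7% at 6 months, 43.2% at 12 months and 49.9% in the unsorted library.

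Perinatal radial glia genes were lower in the lineage after 2 weeks, while its mix of classes differed as well. Astrocytes and NSCs were 35.2% of it at 2 weeks, 19.6% at 2 months, 43.2% at 12 months and 49.9% in the unsorted library. All 12 measured members were lower at 2 months than at 2 weeks in the lineage (median log2 ratio -1.48, against 0.69 between the unsorted 2-month libraries; -0.64 with the unsorted library as 2 months), and all 12 at 12 months (median -0.60, below that spread in size). Fabp7, the fatty acid binding protein of radial glia, stood at 1179, 236, 311 and 232 CPM in order of age (5.08-fold lower at 12 months than at 2 weeks, CI 3.95–6.63), Tnc, a matrix protein of the niche, at 82.4, 11.05, 12.5 and 10.7 (7.69-fold, 2.53–38.1), and Fgfbp3 at 73.7, 23.9, 16.7 and 14.3 (5.16-fold). Fam111a, which counters stalled replication forks, stood at 61.8, 58.9, 66.7 and 3.57 (17.3-fold, 2.98–695), and Arf6 at 61.8, 79.2, 37.5 and 7.14. All 16 cholesterol synthesis genes were lower at 12 months than at 2 weeks (median -0.60, percentile 0.06, against 0.42). Tex10, Snf8 and Mospd3 were 5.66-fold to 7.59-fold lower.

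Other single genes were higher in the lineage at 12 months. Neat1, a nuclear long noncoding RNA, stood at 33.6, 88.4, 110.5 and 225 CPM (6.70-fold over 2 weeks, CI 4.29–10.7), C4b, complement component 4, at 22.8, 23.9, 33.4 and 129 (5.65-fold, 3.21–10.2), Wls, which carries Wnt proteins to the cell surface, at 47.7, 51.6, 85.5 and 221 (4.64-fold, 3.10–6.996), and Prex2 at 33.6, 27.6, 41.7 and 132 (3.93-fold, 2.37–6.56). Over 2 months, Gabrb1, a GABA receptor subunit, was 4.81-fold higher (2.98–7.99), Fut9 4.52-fold, Slco1c1 4.22-fold and Hes1, a Notch target, 4.17-fold, and their levels at 2 weeks (94.3, 137, 183 and 185) were above those at 2 months (46.0, 38.7, 42.4 and 36.8), as was the share of astrocytes and NSCs in the lineage (35.2% against 19.6%, and 43.2% at 12 months). Interferon response genes were higher at 2 months than at 2 weeks for 13 of 13 (median log2 ratio 2.22, against -0.61; 1.16 with the unsorted library as 2 months and 3.09 without cluster 15, which held 2 cells at each of these ages), with Ifi27 at 54.2, 328, 273 and 211. At 12 months 5 of 7 measured members were above 2 weeks (median 1.72), a median that was 0.43 by the mean of per-cell values. Against 2 months 12 of 14 were lower at 12 months (median -0.66), but the median was 0.00 with the unsorted library as the 2-month reference. Mitochondrially encoded genes were higher at 12 months than at 2 weeks for 19 of 21 (median 0.72, against -0.64), and made up 1.77% and 2.82% of the UMIs of all cells at these ages.

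Myelin transcripts lay in lineage cells too, and were higher at 12 months for 11 of 11 genes (median log2 ratio 2.23). In order of age Mal stood at 15.2, 103, 87.6 and 171 CPM, Ptgds at 9.75, 139.9, 123 and 239, and Apod at 4.33, 88.4, 100.1 and 382 (88.1-fold, CI 33.4–329). The myelin list summed to 671, 2519, 2517 and 2860 CPM in lineage cells and to 586, 6594, 2866 and 3259 in microglia of the same libraries, at median depths of 941 and 1136 UMIs at 12 months. Lineage cells of GFP high, a library with no oligodendrocytes, held 222 CPM of the list.

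Within the astrocyte and NSC class the perinatal genes showed a larger difference. All 11 measured members were lower at 12 months than at 2 weeks (median log2 ratio -1.12, percentile 0, against 0.10 between the unsorted 2-month libraries). Cluster 4 made up 43.1% of the class at 2 weeks and 13.04% at 12 months, and cluster 1 made up 56.0% and 87.0%. Fabp7 stood at 2815, 492, 405 and 187 CPM (15.05-fold lower at 12 months, CI 9.21–26.5), Tnc at 243, 68.4, 54.0 and 23.4 (10.4-fold, 2.77–87.6), Fxyd6 at 459, 232.5, 80.9 and 35.1 (13.1-fold, 4.38–64.2) and Dbi, which binds acyl-CoA, at 6301, 4431, 2913 and 1941. Neat1 was 5.61-fold higher at 12 months (3.50–9.13), C4b 4.97-fold (2.76–9.09), H2-K1, an MHC class I heavy chain, 3.11-fold (1.71–5.63), Mgst1 3.01-fold, and Appl2 3.02-fold, and Mertk, a phagocytic receptor, stood at 129, 191, 153 and 386 CPM. Glycolysis genes were higher for 11 of 12 (median 0.74, percentile 99.9), with Gapdh at 191, 205, 279 and 514.5, and cholesterol synthesis genes were lower for 13 of 15 (median -0.61), with Hmgcs1 at 518, 205, 171 and 164. Ribosomal protein genes were lower for 66 of 83 (median -0.41), a median that was -0.14 at a minimum of 1000 UMIs.

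Genes of quiescence did not move together between 2 and 12 months. Of 16 measured genes of quiescent NSCs in this class 8 were higher and 8 lower at 12 months (median log2 ratio 0.00, interval of the median -0.10 to 0.14), and the median was 0.43 with the unsorted library as the 2-month reference. In order of age Id4 stood at 973, 1723, 1070 and 725 CPM, S1pr1 at 1272, 1655, 1843 and 1824, and Sparcl1 at 5238, 4390.0, 4757 and 7389. At 12 months Slc1a2, the glutamate transporter, was 1.85-fold higher than at 2 months (1.64–2.11; levels 4942, 4937, 6160 and 9155), Fut9 3.19-fold (1.61–6.87) and Ptprz1, a receptor phosphatase, 2.13-fold (1.53–3.01; 2169, 697, 1115 and 1485). H2afv, a histone variant, was 4.36-fold lower (2.20–9.40), Etfb 4.01-fold, Syf2 3.78-fold, Dynll1 3.18-fold, Fxyd1 2.39-fold and Dbi 2.28-fold (1.89–2.77). Between these ages cluster 4 made up 30.3% of the class at 2 months and 13.04% at 12 months (6.93–21.7%), and cluster 1 made up 67.7% and 87.0%.

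In microglia, MHC class I and interferon response genes were higher at 2 months than at 2 weeks and lower again at 12 months. From 2 weeks to 2 months 17 of 18 measured genes were higher (median log2 ratio 1.49, percentile 100, against -0.58 between the unsorted 2-month libraries; 0.63 with the unsorted library as 2 months), and at 12 months 16 of 18 were lower than at 2 months (median -0.85, interval of the median -1.16 to -0.49). In order of age H2-D1, an MHC class I heavy chain, stood at 736, 1920, 2216 and 1121 CPM, H2-K1 at 236, 714, 735 and 534, Ifitm3 at 14.3, 281, 384 and 104, and B2m, the light chain, at 4172, 5488, 5774 and 5448. Of 15 genes measured between 2 weeks and 12 months 12 were higher at 12 months (median 0.47, or 1.08 at a minimum of 1000 UMIs per cell). The median of 12 over 2 months was -0.42 without a minimum of UMIs per gene, and its direction turned, to 0.15, with the unsorted library as the 2-month reference.

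Other transcripts of microglia also differed with age. Fcrls, a microglial scavenger receptor, stood at 2193, 724, 511 and 456 CPM (4.81-fold lower at 12 months than at 2 weeks, CI 3.38–7.03), Crybb1 at 1143, 281, 277 and 339 (3.37-fold, 2.22–5.32), Sparc at 8044, 3568, 2897 and 3689 (2.18-fold, 1.91–2.49), Sgk1 at 1179, 452, 341 and 508, and Lrp1 at 864, 492.5, 213 and 326. The chemokine Ccl12 stood at 214, 533, 959 and 808 (3.77-fold higher, 2.40–6.04), Gpr84 at 150.02, 100.5, 117 and 417 (2.78-fold, 1.55–5.07), the protease Ctss at 5622, 9709, 10024 and 10180 (1.81-fold, 1.64–2.00), the protease inhibitor Cst3 at 37305, 46949, 48596 and 66814 (1.79-fold, 1.72–1.86) and Fth1, ferritin heavy chain, at 1393, 3287, 3387 and 2854 (2.05-fold). Of 13 chemokines and cytokines 10 were higher at 12 months than at 2 weeks (median log2 ratio 0.54, against 0.24). Homeostatic genes went both ways (5 higher and 7 lower, median -0.16), with Cx3cr1 at 5301, 4664, 4943 and 5696. Disease-associated genes did so as well (3 higher and 4 lower against 2 weeks, median -0.01, or 1.45 without a minimum of UMIs per gene), and Apoe, one of them, stood at 2172, 4463, 3803 and 2164, 2.06-fold lower at 12 than at 2 months (1.72–2.48). Cd63 and Klf2 were 4.07-fold and 4.01-fold lower at 12 than at 2 months. UMIs of myelin genes in microglia were higher at 12 months than at 2 weeks for 9 of 9 genes (median 2.60), beside 31.5% and 0.545% oligodendrocytes in these libraries, and stood at 3259 and 586 CPM against 2860 and 671 in the stem cell lineage.

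Oligodendrocytes, compared between 2 and 12 months, held fewer transcripts of cholesterol synthesis at the later age, a list singled out here after its values were seen. Of 15 measured genes 14 were lower at 12 months, 10 with an interval below no difference (median log2 ratio -1.58, percentile 0, against -0.28 between the unsorted 2-month libraries). At 6 months 13 of 15 were lower (median -0.89), in a comparison that was not among those fixed beforehand. At 2, 6 and 12 months Hmgcs1, of the early pathway, stood at 434, 171 and 127 CPM, Fdft1, which commits the pathway to sterols, at 151.5, 83.4 and 32.9 (4.60-fold lower, CI 2.08–12.0), Sqle at 89.1, 39.4 and 14.1, and Msmo1 at 395, 178 and 132, while Dhcr7 stood at 59.4, 83.4 and 113. The 11 myelin genes were all slightly lower (median -0.43, against -0.34), with Mbp at 9035, 9984 and 7378, and that median was -0.19 against the unsorted library. Ribosomal protein genes were higher for 80 of 88 (median 0.66) and mitochondrially encoded genes for 15 of 16 (median 1.02, or 0.38 against the unsorted library). Immediate early genes were higher for 7 of 9 (median 1.04), with Fos at 44.5, 341 and 165 (3.69-fold, 1.97–7.28), but the median was 0.40 by the mean of per-cell values, 0.19 at a minimum of 50 UMIs per gene and 0.14 without cluster 18. That small cluster, led by genes of this list, held 0, 11 and 1 of the cells at these ages.

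Single genes of oligodendrocytes with large ratios between 2 and 12 months included Pttg1, securin, at 32.7, 23.2 and 235 CPM (7.20-fold higher, CI 3.70–15.3), Hmgn2, a nucleosome-binding protein, at 134, 116 and 442 (3.31-fold, 2.29–4.83), Agap1 (3.87-fold), Synm (3.17-fold), Nrbp2 (3.12-fold) and Dstn (3.02-fold). Terf2ip, a telomere protein, stood at 169, 60.2 and 28.2 (6.00-fold lower, 2.59–17.0), Ypel3 at 558, 378 and 136 (4.09-fold, 2.76–6.28), Fscn1, which bundles actin, at 241, 192 and 56.4 (4.26-fold, 2.31–8.59) and Capns1 at 353, 285.0 and 98.7. Ptov1, Mrps12, Ube2l3 and Rab33a were 3.53-fold to 4.63-fold lower. Oligodendrocytes at 2 weeks were too few (5 cells) for a ratio.

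**Figure D4:**
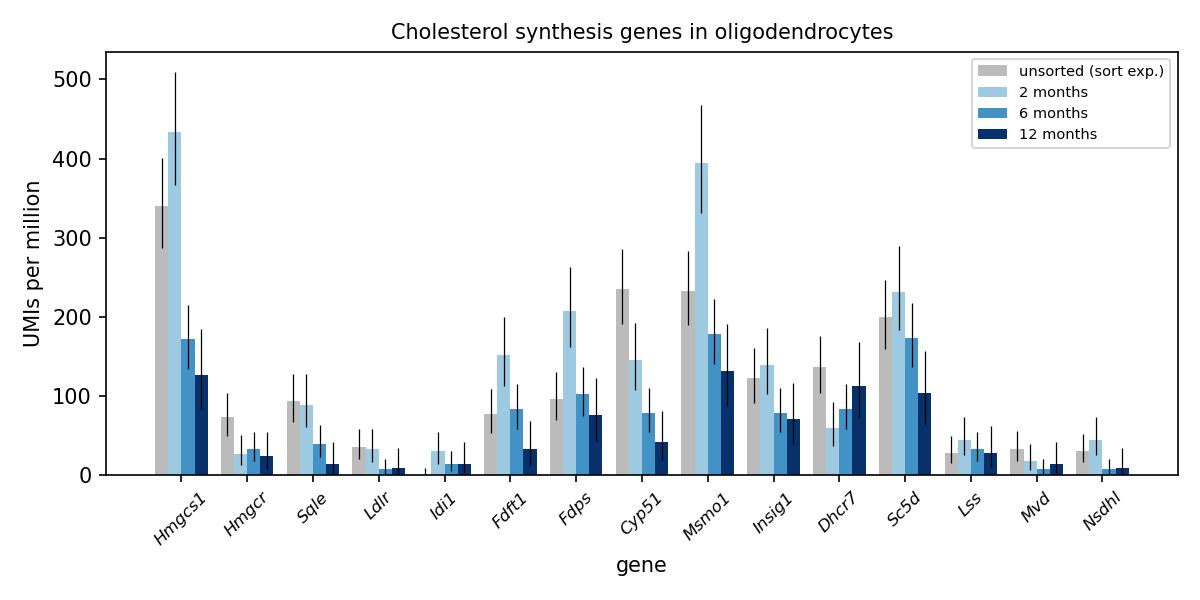
Transcripts of 15 cholesterol synthesis genes in oligodendrocytes (vertical axis, CPM) in the unsorted 2-month library and at 2, 6 and 12 months, as bars per gene with exact Poisson 95% intervals. Hmgcs1 stood at 434 CPM at 2 months and 127 at 12 months, and Dhcr7 went the other way, at 59.4 and 113.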

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

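Of the tests and alternatives in this part, those on the sex of the animals in the lineage of the unsorted library, on a few responding cells and on droplets that hold a pair of cells were set before their results were seen, and all others here were chosen after the result was seen.

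The immediate early and dissociation list drew attention because it moved apart between classes from 2 to 6 months, a ratio of ages not among those fixed beforehand. Its median log2 ratio was 1.83 in oligodendrocytes and -1.17 in mature neurons, a difference of 2.997 that was not tested and that was 1 among 77 combinations of list and age ratio, each with 2 or more classes, that were looked through. The value in oligodendrocytes was 0.39 (0.395) without cluster 18, which is led by genes of this list and held 0 of 292 cells at 2 months and 11 of 439 at 6 months. The value in mature neurons turned to 0.11 by the mean of per-cell values and to 0.39 with the unsorted library as 2 months.

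Reporter UMIs also lay in the barcodes left out for having fewer than 400 UMIs, a signal outside the cells compared in the report. There were 67 such UMIs in GFP high (268 barcodes, 773 CPM), 19 in GFP low (192 barcodes, 301 CPM), 30 in the unsorted library (589 barcodes, 186 CPM), 9 at 2 weeks (76 barcodes, 372 CPM), 16 at 2 months (251 barcodes, 205 CPM) and 6 at 6 months (184 barcodes, 98.1 CPM), while GFP negative and 12 months held no more than 3.

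The reporter transcript, whose identity with the row CGD1 is inferred, was lower at 12 months than at 2 weeks in the stem cell lineage, 9.15-fold (CI 5.18–17.9). Another mix of classes is argued against by the fold within the astrocyte and NSC class alone, 18.2 (6.14–89.2), and a library in which no cell carries the transgene by the 100% (73.5–100%) of the reporter's 12 UMIs at 12 months that lay in lineage cells, which hold 42.0% of all UMIs. Within that class cluster 4 held 90 of 209 cells at 2 weeks and 12 of 92 at 12 months, and the reporter was not compared by cluster. A fall shared with the Nes gene is argued against in neuroblasts, on few UMIs. There the fold of Nes was 0.899 (0.324–2.85, 14 and 6 UMIs) and that of the reporter 12.5 (4.14–61.4, 97 and 3 UMIs). At 12 months Nes stood at 58.4 CPM in neuroblasts (21.4–127), against 0 in oligodendrocytes (up to 17.3) and 0 in microglia (up to 48.1). At 2 weeks it stood at 52.5 in neuroblasts (28.7–88.1) and 14.3 in microglia (1.73–51.6). The intervals of neuroblasts and microglia overlap at these ages. Transcripts of Nes do not measure the transgene's own Nestin sequences, so lower output of these cannot be decided from them. In dividing progenitors (Nes 0.997, 0.471–2.35, reporter 3.37) and in astrocytes and NSCs (Nes 22 against 0 UMIs, 2.18-fold with 3 counts for 0 and 1.63 at the lower end, reporter 18.2) a fall shared with Nes and loss of the reporter alone cannot be told apart, since the intervals of the few UMIs overlap. Age and sex of the animals cannot be told apart here, with no UMI of Xist at 2 weeks and none of Eif2s3y at 12 months. Age, sex, lower output of the transgene's own Nestin sequences, and animals of which part lack the transgene, stay open and untested with 1 library per age.

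Interferon response and MHC class I transcripts were higher at 2 months than at 2 weeks in microglia and in the lineage, by a median log2 ratio of 1.49 in microglia. A few strongly responding cells are argued against, since the median was 1.19 (0.93 to 1.69) without the 0.1 of microglia highest in the lists. For sex of the animals, cells with Xist were set against cells with Y-linked UMIs, stratified over the libraries that hold both. The median was -0.82 (-1.12 to -0.29) in the lineage and -0.90 (-1.34 to -0.29) in microglia. The same genes gave 1.77 (1.765) and 1.38 between the ages. These intervals come from drawing cells, not animals. Lineage values were -0.99 (-1.33 to -0.64) in GFP high and -0.65 (-1.03 to -0.20) in GFP low. Their intervals did not overlap that of the unsorted library of the same experiment, so sex cannot be decided from these cells. Single values were higher in the lineage of the unsorted library, 0.63 (0.04 to 1.09), below the 1.94 set beforehand but with the 0.92 of the same 9 genes in its interval, and in microglia of GFP negative, 0.20 (-0.98 to 0.65, 3 genes), and at 2 weeks, with no UMI of Xist, sexes could not be compared. A difference between libraries cannot be told apart from age. The unsorted 2-month library stood above 2 weeks by 0.63 (0.38 to 1.28), a range that holds the 0.58 between the libraries of that age. Age stays open as untested, and sex as undecided.

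Myelin transcripts were higher at 12 months than at 2 weeks in lineage cells (2860 and 671 CPM). Droplets with an oligodendrocyte and a lineage cell are argued against as the main source, since the 10 lineage cells with 10 or more myelin UMIs held 20.5% of them (17.7–23.4%). Free RNA of oligodendrocytes is a possible source, since microglia held 1.14 times the lineage level at 12 months (0.985–1.31), 586 against 671 CPM at 2 weeks and 2866 against 2517 at 6 months, and lineage cells of GFP high, with no oligodendrocytes, held 222. Values that go against it are those at 2 months, where microglia held 6594 and the lineage 2519, and those of GFP low, whose lineage held 357 beside 4.40% oligodendrocytes, below the 671 at 2 weeks beside 0.545%. Myelin transcripts made by lineage cells with age stay open as untested.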

How the results depend on the processing

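Of the alternatives in this part, another random start, the minimum of 200 and the maximum of 4000 UMIs per cell, 15 principal components for the share of dividing progenitors, all settings for lists other than the planned ones, medians without clusters 15 and 18, and other depths of thinning together with other minimums of cell cycle UMIs were chosen after the data were seen. No paired analysis was possible because each group was 1 library, and no test was run. The cause of the changes below was not tested. The astrocyte and NSC share of GFP high over GFP negative (35.0) was at least 57.0 at a minimum of 1000 UMIs per cell, the neuroblast share of GFP low over GFP negative (10.4) was 6.76 there and the microglia share of GFP negative over GFP high (212) at least 10.7. The dividing progenitor share of GFP low over GFP high (3.64) was 2.54 at that minimum, 6.45 with 15 principal components and 5.85 with the sort and age libraries clustered separately. The share of dividing progenitors in the lineage (0.630) and that of neuroblasts (1.03) at 12 months over 2 weeks moved beyond their intervals under none of the alternatives run. The share with cell cycle UMIs (0.502) did so only for at least 1 UMI after thinning to 800 UMIs (0.844). Its interval reached past no difference after thinning to 200 UMIs (0.584, 0.314–1.04) and to 800 UMIs (0.688, 0.440–1.04). Thinning to 800 UMIs also left out the cells with fewer UMIs, so these values rest on another set of cells.

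The median of the cell cycle lists in the lineage at 12 months over 2 weeks (-0.33) was -0.76 by the mean of per-cell values, -0.21 by median of ratios and -0.11 at a minimum of 1000 UMIs. The quiescent NSC median at 12 over 2 months (0.00) was 0.43 with the unsorted library as 2 months. The median of MHC class I and interferon lists in microglia at 12 over 2 months (-0.85) was -0.42 with no minimum of UMIs per gene and turned to 0.15 with the unsorted library as 2 months. Other turns of direction were the interferon list in the lineage at 12 over 2 months, from -0.66 to 0.00 (0.00499) with the unsorted library, and the immediate early list in mature neurons at 6 over 2 months, from -1.17 to 0.11 by the mean of per-cell values and 0.39 with the unsorted library.

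Of class shares per library 104 moved and 600 did not under the alternatives fixed beforehand, and 11 moved and 253 did not under those added. A minimum of 1000 UMIs moved 48 of the 88 shares, classing each cell on its own 28, and separate clustering 16. Of the other list medians 53 moved, 3 turned and 422 did neither, and of named genes 21 moved and 1001 did not. A minimum of 50 UMIs per gene was not run for the G2/M list in the astrocyte and NSC class, the interferon lists in the lineage and the myelin list in microglia, and a minimum of 1000 UMIs per cell was not run for the quiescent NSC list in the astrocyte and NSC class and the immediate early list in mature neurons, each for too few genes or cells. Depth limits the text: 36.4% of the 11017 barcodes in the files held at least 1000 UMIs, and the simulated recovery of 2-fold changes was 27% to 40%.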

Other observations

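Genes named here outside the rule were chosen after their values were seen, and no test was run in this part. In microglia, inflammatory transcripts were uneven with age. In order of age (2 weeks, 2, 6 and 12 months), the chemokine Ccl2 stood at 78.6, 60.3, 107 and 261 CPM, the cytokine Tnf at 42.9, 20.1, 95.9 and 313, Ccl4 at 1050, 1136, 1768 and 1525, and Ccl3 at 657, 744, 948 and 952. The homeostatic receptor P2ry12 stood at 6751, 4101, 3845 and 4940, Tmem119 at 1729, 1578, 1502 and 1121, and Siglech at 1872, 1648, 1694 and 2281.

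Genes of dorsal and ventral position were higher in GFP high than in GFP negative for 11 of 13 (median log2 ratio 3.14), and than in GFP low for 9 of 13 (1.30). Ptov1 was 3.57-fold lower at 12 months than at 2 weeks in neuroblasts (CI 2.09–6.55) and 4.20-fold lower at 12 than at 2 months in dividing progenitors (2.05–10.01).

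Hemoglobin transcripts made up 0.904% of UMIs at 2 weeks, 0.518% at 2 months, 3.18% at 6 months and 2.61% at 12 months, and erythrocytes 1.09%, 0.507%, 2.91% and 2.53% of cells. Cluster 18, of the oligodendrocyte class and led by immediate early genes, held 11 of its 21 cells at 6 months. The cell with 434 Ttr UMIs in GFP negative held 1145 UMIs and 20 of Enpp2, another choroid plexus transcript.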
